A study of Homo sapiens with 16 samples.

How the data were processed

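A549 cells that overexpressed CD63-Nluc were treated with DMSO, 5G6, 6D7 or 7F8 for 4 h or 48 h, and polyA RNA was sequenced. Per the labels, RNA was extracted with TRIzol, treated with DNase I, and made into libraries with a NEBNext Ultra kit from 1 µg per sample. Strandedness was not stated. The labels' processing notes name STAR 2.6.1a, featureCounts 1.6.3 and StringTie 2.0 with GRCh38, without the order or role of each.

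Each library had 1 deposited gene abundance table with the columns of StringTie. TPM values were made by the authors with StringTie before deposit, scaled by length-normalized coverage to the same sum in each library, mitochondrial genes included. FPKM values were made by the authors with StringTie, scaled by gene length and aligned fragments, and are a constant multiple of TPM within a library. Coverage values are, per the file headers, the mean read coverage of each gene without scaling between libraries. No read counts were used. Coverage and FPKM together gave 6.10 to 8.86 aligned gigabases per library, and 13013 to 14568 genes had TPM of at least 1. The 10 highest genes took 10.8 to 36.4 percent of TPM and mitochondrial genes 6.13 to 32.5 percent. The FPKM of TRNC was 66.0 times that expected from its coverage, and its length is 66 bases. MALAT1 and NEAT1 were listed at 0 in all 16 libraries. Identical TPM values made up at most 0.0384 percent of genes between any pair of libraries. Principal components 1, 2 and 3 of log2(TPM + 1) took 33.2, 20.4 and 11.5 percent of the variance.

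Values of a gene listed at several places were added. Of 26182 genes with TPM above 0, the 15285 with TPM of at least 1 in at least 2 libraries were tested. The values log2(TPM + 1) of all 16 libraries were fitted with limma 3.58.1 in R 4.3.3, with 8 group means, 8 residual degrees of freedom and empirical Bayes moderation with a mean-variance trend (median prior degrees of freedom 3.94). Tests were two-sided, adjusted by Benjamini-Hochberg within each of 16 comparisons and called at an adjusted p below 0.05. The comparisons were each compound against DMSO at each time, the compounds against each other at each time, the effect of each compound at 48 h minus that at 4 h, and DMSO at 48 h against 4 h. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

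Before the data were examined, 28 lists of 781 genes were written from general knowledge. The 26 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 26 lists of a comparison, and again with an estimated correlation. The value of a list is the median log2 fold change of its members. Intervals at 95% for the mean of a list between compounds came from the same residual degrees of freedom after median-of-ratios scaling and carry no p.

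Named genes followed a rule written in advance. Eligible genes had a gene name other than a clone name, a mean TPM of at least 5 in the higher group, and both libraries of one group above both of the other. For each compound against DMSO the rule took the 6 largest called rises and the 6 largest called falls, and the 3 members with the smallest p in each called list. Between compounds it took the 4 largest called differences each way, and for time differences the 3 largest each way. It always took SREBF1, SREBF2, HMGCS1, INSIG1, SQLE, FASN, SCD, ABCA1, CD63, RAB27A, PRKAA1, TXNIP, DDIT3, CDKN1A and HMOX1, and 2 more genes that are not reported here. The text prints a part of the list, between-compound and fixed genes.

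Alternatives set in advance were FPKM in place of TPM, a pseudocount of 0.1, no filter, median-of-ratios scaling (size factors 0.817 to 1.35), variance without the trend, the libraries of 1 time point alone, a replicate block (7 residual degrees of freedom), leaving out each library in turn and an estimated correlation in the list test. Others, named below, were added after the data were seen. The overlap between compounds was compared with 50 simulations of unchanged groups against shared DMSO libraries.

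The procedure was tested on simulated data of the same size for 5G6 against DMSO at 48 h, with 200 of 15285 genes changed. It called 33 of 100 genes changed 2-fold (median estimate 1.06 on the log2 scale) and 87 of 100 changed 4-fold (2.01). Of 125 calls 5 were unchanged genes, 4 percent, and 3 genes were called in comparisons without the changed group. A list shifted by 0.5 was called and 0 of 25 others were, which does not test correlated genes. Groups of 2 were too small to test outliers or splits.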

Results

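Human A549 lung cancer cells that overexpressed CD63-Nluc, a fusion of the exosome membrane protein CD63 with the Nluc luciferase reporter, were given the solvent DMSO or 1 of 3 compounds. The compounds carry the code names 5G6, 6D7 and 7F8, and their structures were not given. Cells were collected after 4 h or 48 h, and the labels print 4 µM for every treatment, DMSO included. Each of the 8 groups held 2 biological replicates by the series description, 16 RNA libraries in all. The series title names exosome release, AMPK and SREBPs. AMPK is a kinase that senses low cellular energy, and SREBPs are transcription factors that switch on sterol and fatty acid synthesis. The study therefore bears on lipid, exosome and growth genes in a lung cancer line.

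Expression was read from deposited gene abundance tables in TPM. All 16 libraries entered 1 limma fit on log2(TPM + 1) with 8 group means. The 15285 genes with TPM of at least 1 in at least 2 libraries were tested. A gene was called at a Benjamini-Hochberg (BH) adjusted p below 0.05 within its comparison, and these p-values measure the spread between these samples. Log2 fold changes are on the log2(TPM + 1) scale, which understates change in weakly expressed genes. Prepared lists of genes with a common function were tested with camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. Of the 156 list tests against DMSO, 79 were called with the preset correlation and 1 with the estimated correlation. Estimated correlations rest on 8 degrees of freedom.

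The mitochondrial tRNA genes TRNC and TRNY shaped the TPM scale. TRNC took 15.3 to 28.6 percent of all TPM in 14 libraries and was listed at 0 in both 6D7 libraries at 48 h. That is not its share of reads, because its FPKM was 66.0 times that expected from its coverage. There the neighbouring TRNY gene was listed at 5984 and 4738 TPM, and it was listed at 0 in the other 14. In mean read coverage the 2 genes exchanged places: TRNC coverage ran from 9556 to 17927 where TRNC was listed, and TRNY coverage was 15808 and 12904 in the 2 libraries of 6D7 at 48 h. Both genes lie on the minus strand of chromosome M, TRNC at 5761 to 5826 and TRNY at 5826 to 5891 (GRCh38). TPM values sum to a fixed total, so a smaller TPM of this locus raises the TPM of all other genes. The median over all tested genes was 0.29 for 6D7 against DMSO at 48 h, -0.06 with TPM recomputed without TRNC and TRNY, and 0.02 after median-of-ratios scaling, which centres it. For 7F8 at 48 h it was -0.21 and 0.00, and for 5G6 and 7F8 at 4 h it was 0.13 and -0.10 before scaling, 0.01 and -0.03 after it. Median-of-ratios medians therefore stand beside list medians on TPM.

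**Figure D1:**
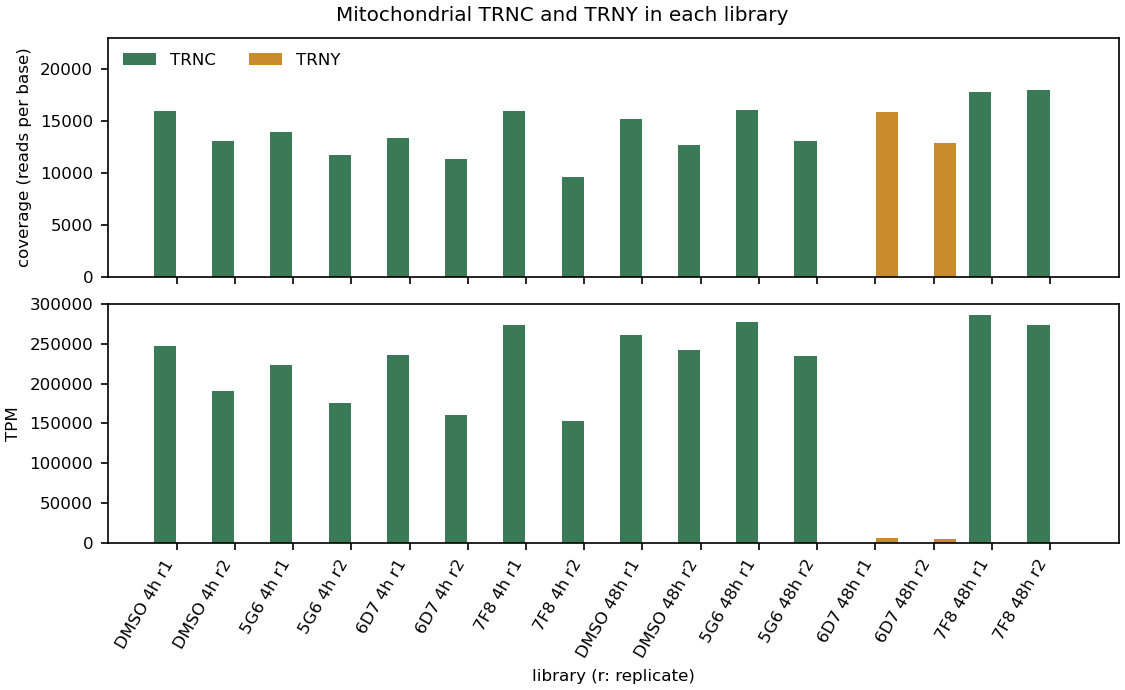
Coverage and TPM of the mitochondrial tRNA genes TRNC and TRNY in each of the 16 libraries.

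Few single genes separated from DMSO at 4 h, and many did at 48 h. At 4 h limma called 3 genes with 5G6, 0 with 6D7 and 0 with 7F8. Unadjusted p was below 0.05 in 597, 180 and 743 genes (956, 316 and 1466 with a replicate block). At 48 h it called 517 genes with 5G6 (286 higher, 231 lower), 1899 with 6D7 (1666 higher, 233 lower) and 1297 with 7F8 (318 higher, 979 lower). After median-of-ratios scaling the splits were 395 higher and 229 lower, 503 and 505, and 566 and 618. Genes called in one direction under both scalings numbered 452, 732 and 926. At least 2-fold change was seen in 410, 1290 and 909 of the TPM calls. With a replicate block, which the labels do not give, limma called 1739 (704 higher, 1035 lower), 3806 (3210, 596) and 2944 (685, 2259). After median-of-ratios scaling the block gave 1654 (915, 739), 2131 (1128, 1003) and 2401 (1236, 1165).

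**Figure D2:**
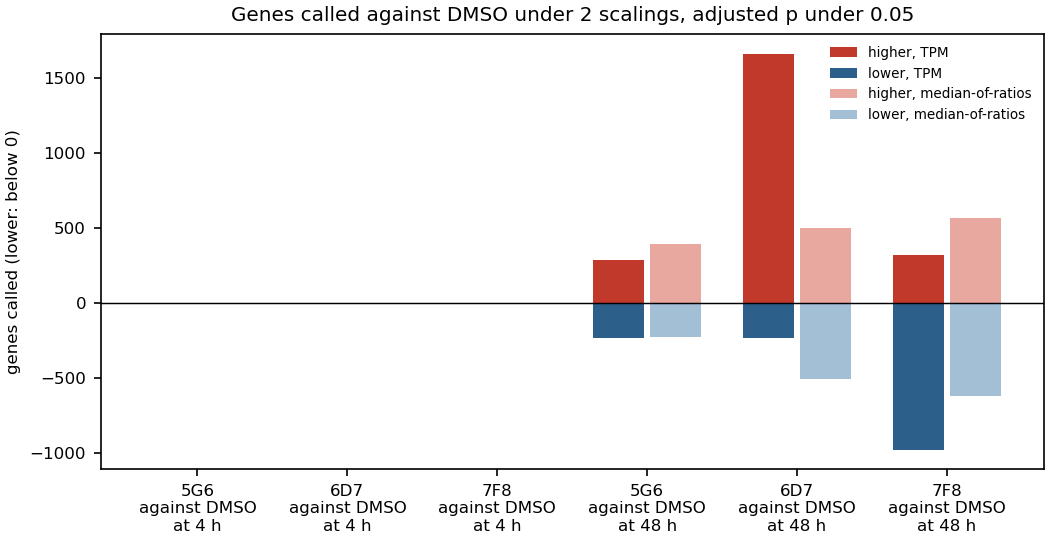
Genes called higher and lower than DMSO for each compound and time, on TPM and after median-of-ratios scaling.

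5G6 shifted the sterol, fatty acid, lysosome and ATF4 lists upward within 4 h, with 1 member called by limma and no list called with an estimated correlation. Genes that answer to SREBP2 filled the sterol list (median log2 fold change 1.59 over 26 members, 1.45 after median-of-ratios scaling, camera BH-adjusted p = 3.6e-39, adjusted p = 0.0831 with an estimated correlation). It had 0 of 26 members called by limma, with 22 higher and 0 lower adjusted over the list alone. INSIG1, an endoplasmic reticulum anchor that restrains SREBP, stood at 29.3 ± 12.3 and 203 ± 19.1 TPM (SD, n = 2) in DMSO and 5G6, with a log2 fold change of 2.81 ± 0.59 (SE) and a limma BH-adjusted p of 0.229. The fatty acid list moved upward as well (median log2 fold change 0.82 over 20 members, 0.68 after median-of-ratios scaling, camera BH-adjusted p = 3.2e-15, adjusted p = 0.160 with an estimated correlation), and it had 0 of 20 members called by limma, with 8 higher and 0 lower adjusted over the list alone. FASN, which builds palmitate, had 68.4 ± 11.9 and 285 ± 48.6 TPM (SD, n = 2) (log2 2.04, limma BH-adjusted p = 0.275). LPIN1, a phosphatidate phosphatase, had 10.6 ± 2.43 and 60.3 ± 10.6 TPM (SD, n = 2) (log2 2.40, limma BH-adjusted p = 0.0941).

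The 3 genes called with 5G6 at 4 h were all higher than in DMSO, and 2 of them act at the lysosome. FLCN, a tumour suppressor that passes lysosomal nutrient signals to TFEB, rose from 15.7 ± 0.708 to 51.6 ± 7.94 TPM (SD, n = 2), log2 fold change 1.65 ± 0.20 (SE), limma BH-adjusted p = 0.0287. PIP4P1, a lysosomal phosphoinositide phosphatase, rose from 35.8 ± 1.53 to 81.8 ± 0.231 TPM (SD, n = 2), log2 fold change 1.17 ± 0.15 (SE), limma BH-adjusted p = 0.0329. Its limma BH-adjusted p after median-of-ratios scaling was 0.232. UAP1L1, a relative of an enzyme that makes UDP-sugars, rose from 5.01 ± 0.153 to 30.4 ± 2.35 TPM (SD, n = 2), log2 fold change 2.38 ± 0.29 (SE), limma BH-adjusted p = 0.0287. Leaving out DMSO replicate 1, DMSO replicate 2, 5G6 replicate 1 or 5G6 replicate 2, limma called 0, 0, 2 and 1 genes, and none of these 3 genes. Lysosome and autophagy genes under TFEB moved upward (median log2 fold change 0.42 over 45 members, 0.28 after median-of-ratios scaling, camera BH-adjusted p = 1.7e-18, adjusted p = 0.0831 with an estimated correlation). It had 1 member called higher, 0 lower and 44 not called, with 12 higher and 0 lower adjusted over the list alone. Genes under ATF4, the factor of the integrated stress response, did so too (median log2 fold change 0.43 over 38 members, 0.29 after median-of-ratios scaling, camera BH-adjusted p = 1.6e-07, adjusted p = 0.209 with an estimated correlation). The ATF4 list had 0 of 38 members called by limma, with 3 higher and 0 lower adjusted over the list alone. TRIB3, a pseudokinase that ATF4 induces, had 73.5 ± 3.498 and 339 ± 45.9 TPM (SD, n = 2) (log2 2.19, limma BH-adjusted p = 0.123). CD63 was not called, at 1144 ± 77.2 and 1659 ± 259 TPM (SD, n = 2) (log2 0.53, limma BH-adjusted p = 1).

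6D7 shifted the list of stress genes under ATF4 upward at 4 h, and the sterol list without a single called gene. The ATF4 list was the only list against DMSO to be called with both kinds of correlation (median log2 fold change 0.67 over 38 members, 0.62 after median-of-ratios scaling, camera BH-adjusted p = 4.0e-39, adjusted p = 0.00642 with an estimated correlation). It had 0 of 38 members called by limma, with 6 higher and 0 lower adjusted over the list alone. Without 6D7 replicate 2 its median was 0.39. TRIB3 had 73.5 ± 3.498 and 303 ± 35.9 TPM (SD, n = 2) (log2 2.02, limma BH-adjusted p = 0.554). ASNS, the asparagine synthetase that ATF4 induces when amino acids run short, had 31.7 ± 3.45 and 65.7 ± 23.9 TPM (SD, n = 2) (log2 0.98, limma BH-adjusted p = 1). Among sterol genes (median log2 fold change 0.84 over 26 members, 0.79 after median-of-ratios scaling, camera BH-adjusted p = 7.3e-26, adjusted p = 0.154 with an estimated correlation), the list had 0 of 26 members called by limma, with 0 higher and 0 lower adjusted over the list alone, and its median was 0.56 without 6D7 replicate 1. INSIG1 had 29.3 ± 12.3 and 109.7 ± 44.2 TPM (SD, n = 2) (log2 1.87, limma BH-adjusted p = 1). Lysosome genes shifted upward (median log2 fold change 0.28 over 45 members, 0.22 after median-of-ratios scaling, camera BH-adjusted p = 1.2e-21, adjusted p = 0.0551 with an estimated correlation). Lysosome genes had 0 of 45 members called by limma, with 4 higher and 0 lower adjusted over the list alone. FLCN had 15.7 ± 0.708 and 40.2 ± 5.25 TPM (SD, n = 2) (log2 1.297, limma BH-adjusted p = 0.296). Heat shock genes shifted downward (median log2 fold change -0.20 over 20 members, -0.26 after median-of-ratios scaling, camera BH-adjusted p = 5.7e-06, adjusted p = 0.489 with an estimated correlation). Heat shock genes had 0 of 20 members called by limma, with 0 higher and 0 lower adjusted over the list alone. No single gene was called by limma with 6D7 at 4 h, and without 6D7 replicate 2 it called 1.

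7F8 at 4 h shifted the list of inflammatory genes under NF-kB upward without a called gene. The NF-kB list had the largest median (median log2 fold change 1.46 over 25 members, 1.55 after median-of-ratios scaling, camera BH-adjusted p = 2.1e-25, adjusted p = 0.143 with an estimated correlation). NF-kB genes had 0 of 25 members called by limma, with 14 higher and 0 lower adjusted over the list alone. Without 7F8 replicate 2 that median was 0.61. SOD2, the mitochondrial superoxide dismutase that NF-kB induces, had 148 ± 20.8 and 634 ± 119 TPM (SD, n = 2) (log2 2.08, limma BH-adjusted p = 0.158). TNFAIP2, a gene induced by tumour necrosis factor, had 153 ± 15.6 and 657 ± 277 TPM (SD, n = 2) (log2 2.03, limma BH-adjusted p = 0.158). CXCL5, a chemokine that draws neutrophils, had 390.1 ± 29.3 and 1200.0 ± 384 TPM (SD, n = 2) (log2 1.58, limma BH-adjusted p = 0.158). The sterol list was not called (median log2 fold change -0.05 over 26 members, 0.04 after median-of-ratios scaling, camera BH-adjusted p = 0.275, adjusted p = 0.956 with an estimated correlation). There were 0 of 26 members called by limma, with 0 higher and 0 lower adjusted over the list alone. Lysosome genes shifted upward by a small amount (median log2 fold change 0.16 over 45 members, 0.25 after median-of-ratios scaling, camera BH-adjusted p = 1.3e-07, adjusted p = 0.446 with an estimated correlation). These had 0 of 45 members called by limma, with 2 higher and 0 lower adjusted over the list alone. SQSTM1, an autophagy receptor, had 716 ± 227 and 1640.5 ± 399.6 TPM (SD, n = 2) (log2 1.21, limma BH-adjusted p = 0.539). No single gene was called by limma, and without 7F8 replicate 1 or 2 it called 19 and 2.

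After 48 h of 5G6 the sterol and fatty acid programs stood high, and many of their genes were called one by one. The sterol list (median log2 fold change 2.23 over 26 members, 2.33 after median-of-ratios scaling, camera BH-adjusted p = 1.6e-28, adjusted p = 0.119 with an estimated correlation) led, and it had 20 members called higher, 0 lower and 6 not called, with 24 higher and 0 lower adjusted over the list alone. INSIG1 rose from 24.7 ± 2.78 to 338 ± 39.6 TPM (SD, n = 2), log2 fold change 3.72 ± 0.59 (SE), limma BH-adjusted p = 0.00991. HMGCS1, an early enzyme of sterol synthesis, rose from 38.8 ± 6.51 to 304 ± 52.0 TPM (SD, n = 2), log2 fold change 2.94 ± 0.59 (SE), limma BH-adjusted p = 0.0250. Other sterol genes called were SQLE (48.6 ± 0.628 to 239 ± 42.3, log2 2.26, adjusted p = 0.0261) and LSS (21.4 ± 1.38 to 151 ± 34.7, log2 2.74, adjusted p = 0.00829), as mean TPM ± SD (n = 2) and limma BH-adjusted p. SQLE oxidizes squalene and LSS closes the sterol ring. Fatty acid genes followed (median log2 fold change 0.88 over 20 members, 0.98 after median-of-ratios scaling, camera BH-adjusted p = 1.1e-09, adjusted p = 0.226 with an estimated correlation). It had 10 members called higher, 0 lower and 10 not called, with 10 higher and 0 lower adjusted over the list alone. ACSS2, which turns acetate into acetyl-CoA, rose from 13.2 ± 2.61 to 214 ± 52.6 TPM (SD, n = 2), log2 fold change 3.91 ± 0.52 (SE), limma BH-adjusted p = 0.00522. FASN and SCD, the desaturase that makes oleate, were called by limma with BH adjustment as FASN (99.4 ± 14.3 to 443 ± 198, log2 2.08, adjusted p = 0.0302) and SCD (558 ± 278 to 4465 ± 2834, log2 2.93, adjusted p = 0.0461), each ± SD (n = 2). The SREBP genes themselves were not called: SREBF2 had log2 1.02 and SREBF1 0.54 (limma BH-adjusted p = 0.0994 and 0.589). Nor was ABCA1, a cholesterol exporter, at log2 -0.15 (limma BH-adjusted p = 0.967), and its LXR list was not called (median log2 fold change 0.26 over 10 members, 0.34 after median-of-ratios scaling, camera BH-adjusted p = 0.206, adjusted p = 0.690 with an estimated correlation). This list had 0 of 10 members called by limma, with 0 higher and 0 lower adjusted over the list alone, and its median was -0.05 without DMSO replicate 1 and 0.82 without DMSO replicate 2, where camera called it.

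5G6 at 48 h shifted lysosome and glycolysis lists up and DNA replication and ribosome biogenesis lists down. Lysosome genes (median log2 fold change 0.81 over 45 members, 0.91 after median-of-ratios scaling, camera BH-adjusted p = 1.3e-22, adjusted p = 0.0970 with an estimated correlation) included NPC1, which exports cholesterol from the lysosome, up from 21.7 ± 0.365 to 149 ± 32.1 TPM (SD, n = 2), log2 fold change 2.70 ± 0.31 (SE), limma BH-adjusted p = 0.00395. That list had 17 members called higher, 0 lower and 28 not called, with 28 higher and 0 lower adjusted over the list alone. Genes of the glycolysis and hypoxia list had a median log2 fold change 1.01 over 35 members, 1.12 after median-of-ratios scaling, camera BH-adjusted p = 5.6e-17, adjusted p = 0.132 with an estimated correlation. The list had 8 members called higher, 0 lower and 27 not called, with 20 higher and 0 lower adjusted over the list alone, and their median was 0.53 without DMSO replicate 1. ALDOC, a glycolytic aldolase, and HK2, a hexokinase, were called by limma with BH adjustment as ALDOC (10.1 ± 5.47 to 198 ± 37.4, log2 4.25, adjusted p = 0.00488) and HK2 (1.29 ± 0.850 to 14.0 ± 3.62, log2 2.74, adjusted p = 0.00630), each ± SD (n = 2). The DNA replication list had a median log2 fold change -1.70 over 39 members, -1.60 after median-of-ratios scaling, camera BH-adjusted p = 3.5e-28, adjusted p = 0.226 with an estimated correlation. The list had 23 members called lower, 0 higher and 16 not called, with 37 lower and 0 higher adjusted over the list alone. MCM5 and MCM6, subunits of the replicative helicase, GINS2, its partner, and MCM10, an initiation factor, were called by limma with BH adjustment as MCM5 (61.0 ± 6.70 to 10.9 ± 0.658, log2 -2.38, adjusted p = 0.0106), MCM6 (55.5 ± 3.92 to 11.3 ± 3.08, log2 -2.22, adjusted p = 0.00932), GINS2 (28.3 ± 5.33 to 4.81 ± 0.530, log2 -2.32, adjusted p = 0.0143) and MCM10 (17.0 ± 1.32 to 2.69 ± 0.905, log2 -2.31, adjusted p = 0.0300). Mitotic genes lay lower as a list (median log2 fold change -1.54 over 30 members, -1.44 after median-of-ratios scaling, camera BH-adjusted p = 8.8e-10, adjusted p = 0.494 with an estimated correlation). This list had 0 of 30 members called by limma, with 0 higher and 0 lower adjusted over the list alone. CDC20, an activator of mitotic exit, had log2 -2.04 (limma BH-adjusted p = 0.0887). Ribosome biogenesis genes had a median log2 fold change -0.82 over 35 members, -0.71 after median-of-ratios scaling, camera BH-adjusted p = 2.7e-18, adjusted p = 0.119 with an estimated correlation. The list had 9 members called lower, 0 higher and 26 not called, with 30 lower and 0 higher adjusted over the list alone. NOP16, a nucleolar assembly factor, fell from 88.4 ± 20.4 to 38.5 ± 3.46 TPM (SD, n = 2), log2 fold change -1.16 ± 0.17 (SE), limma BH-adjusted p = 0.00917. The remaining largest calls were IGFL2-AS1 (3.34 ± 0.954 to 144 ± 82.0, log2 4.96, adjusted p = 0.00463), IGFBP1 (63.5 ± 50.5 to 715 ± 192, log2 3.71, adjusted p = 0.00463), MIR6783 (16.8 ± 6.45 to 1.93 ± 0.686, log2 -2.58, adjusted p = 0.0331) and DDC (6.42 ± 0.639 to 0.675 ± 0.0559, log2 -2.14, adjusted p = 0.00152), by limma with BH adjustment. IGFL2-AS1 is an antisense RNA, and strand was not stated. MIR6783, a microRNA gene, lies within KIF18B on the same strand, so its reads cannot be told from those of KIF18B. IGFBP1 binds insulin-like growth factors and DDC makes dopamine. RNF113A, a splicing factor gene, was listed at 0 in both DMSO libraries at 48 h and in 7F8 replicate 1 at 4 h, and at 19.7 to 61.8 TPM in the other 13 libraries. It lies 3 bases from NDUFA1 on the other strand, so its reads cannot be assigned with certainty.

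Exosome genes moved little with 5G6 at 48 h, and the reporter's parent gene CD63 was not called. The exosome list had a small shift (median log2 fold change 0.10 over 64 members, 0.20 after median-of-ratios scaling, camera BH-adjusted p = 0.00287, adjusted p = 0.350 with an estimated correlation). It had 2 members called higher, 0 lower and 62 not called, with 2 higher and 0 lower adjusted over the list alone. Its median ran from 0.05 without DMSO replicate 1 or 5G6 replicate 2 to 0.23 without DMSO replicate 2. SDCBP, the syntenin scaffold that sorts cargo into exosomes, rose from 125 ± 24.7 to 314 ± 43.0 TPM (SD, n = 2), log2 fold change 1.33 ± 0.28 (SE), limma BH-adjusted p = 0.0292. CORO1B, an actin regulator on that list, rose from 44.8 ± 1.70 to 86.1 ± 10.7 TPM (SD, n = 2), log2 fold change 0.92 ± 0.18 (SE), limma BH-adjusted p = 0.0206. CD63, which at 12:55725443 to 55729673 (minus strand, GRCh38) may collect reads of the fusion transcript, had 1386 ± 103 and 1765 ± 10.4 TPM (SD, n = 2) (log2 0.35, limma BH-adjusted p = 0.408, 0.348 after median-of-ratios scaling). RAB27A, a GTPase for exosome docking, had log2 0.51 and PRKAA1, the catalytic AMPK subunit, -0.38 (limma BH-adjusted p = 0.513 and 0.568). The AMPK list was not called (median log2 fold change -0.01 over 20 members, 0.09 after median-of-ratios scaling, camera BH-adjusted p = 0.810, adjusted p = 0.907 with an estimated correlation). It had 0 of 20 members called by limma, with 0 higher and 0 lower adjusted over the list alone. Messenger RNA does not measure AMPK phosphorylation, SREBP processing or vesicle release. Without DMSO replicate 1, DMSO replicate 2, 5G6 replicate 1 or 5G6 replicate 2, limma called 5, 122, 45 and 40 genes at 48 h. Of the 42 called genes that the naming rule selected, 2, 23, 15 and 13 were called again, and 41 were after median-of-ratios scaling.

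**Figure D3:**
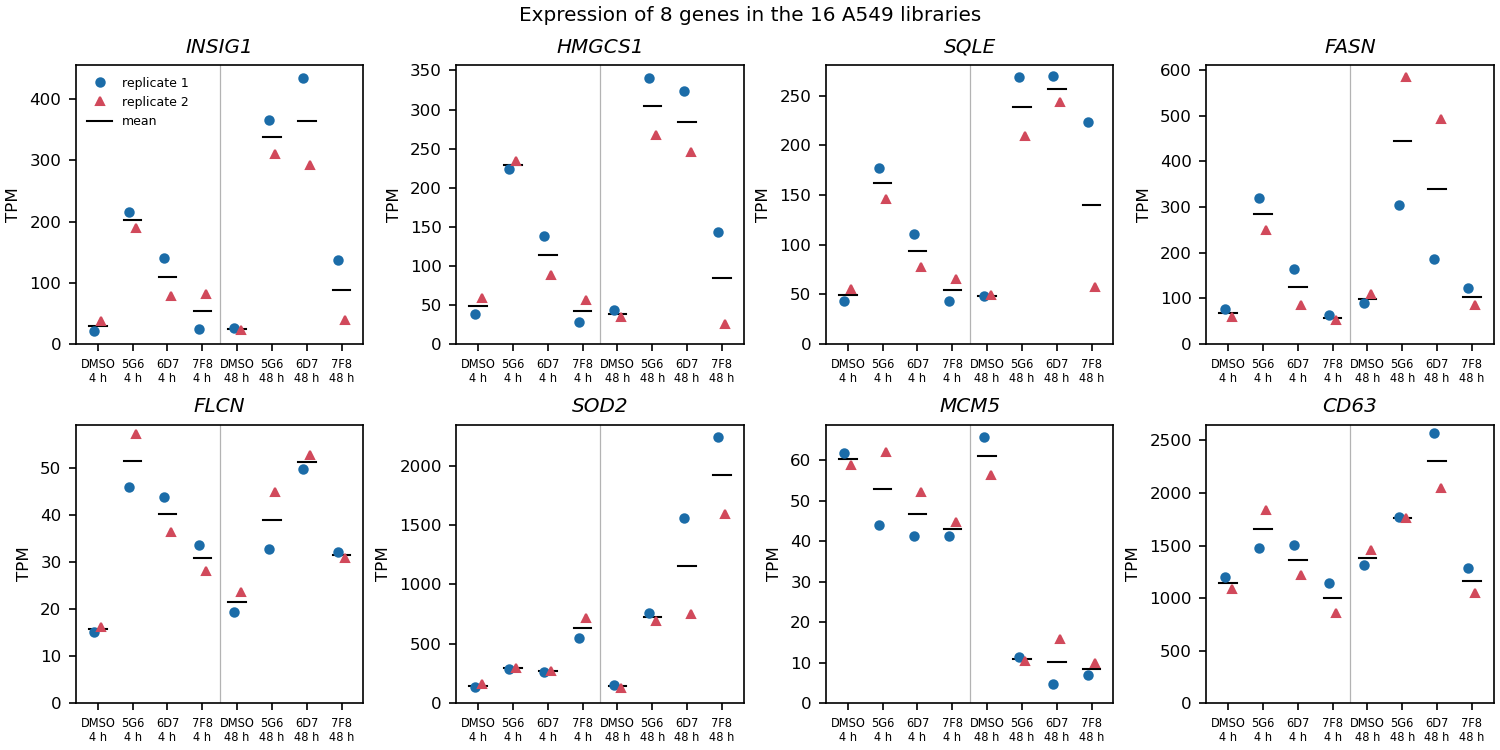
TPM of INSIG1, HMGCS1, SQLE, FASN, FLCN, SOD2, MCM5 and CD63 in each library, with replicate 1 as circles, replicate 2 as triangles and a bar at each group mean.

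6D7 at 48 h shifted the sterol list and the ATF4 and p53 stress lists upward. Sterol genes had a median log2 fold change 2.08 over 26 members, 1.75 after median-of-ratios scaling, camera BH-adjusted p = 4.6e-13, adjusted p = 0.269 with an estimated correlation. The list had 22 members called higher, 0 lower and 4 not called, with 24 higher and 0 lower adjusted over the list alone. After median-of-ratios scaling 15 were called higher. INSIG1 rose from 24.7 ± 2.78 to 364 ± 100.2 TPM (SD, n = 2), log2 fold change 3.81 ± 0.59 (SE), limma BH-adjusted p = 0.00378. HMGCS1 and SQLE were called by limma with BH adjustment as HMGCS1 (38.8 ± 6.51 to 284 ± 55.2, log2 2.84, adjusted p = 0.0129) and SQLE (48.6 ± 0.628 to 256 ± 18.0, log2 2.37, adjusted p = 0.0101), each ± SD (n = 2). SCD, FASN and SREBF2, the gene of SREBP2, were called on TPM only, SCD (558 ± 278 to 3897 ± 3934, log2 2.38, adjusted p = 0.0467), FASN (99.4 ± 14.3 to 339.8 ± 217, log2 1.61, adjusted p = 0.0372) and SREBF2 (49.1 ± 9.98 to 107 ± 7.46, log2 1.13, adjusted p = 0.0353), and their limma BH-adjusted p after median-of-ratios scaling was 0.0962, 0.105 and 0.192. ATF4 genes had a median log2 fold change 0.84 over 38 members, 0.51 after median-of-ratios scaling, camera BH-adjusted p = 0.000244, adjusted p = 0.336 with an estimated correlation. The list had 13 members called higher, 0 lower and 25 not called, with 18 higher and 0 lower adjusted over the list alone. GDF15, a stress cytokine under both ATF4 and p53, rose from 92.7 ± 19.4 to 591 ± 196 TPM (SD, n = 2), log2 fold change 2.63 ± 0.29 (SE), limma BH-adjusted p = 0.000750. p53 targets had a median log2 fold change 0.97 over 25 members, 0.68 after median-of-ratios scaling, camera BH-adjusted p = 2.9e-06, adjusted p = 0.363 with an estimated correlation. The list had 10 members called higher, 0 lower and 15 not called, with 16 higher and 0 lower adjusted over the list alone. CDKN1A, the p21 brake on the cell cycle, rose from 114 ± 7.03 to 523 ± 331 TPM (SD, n = 2), log2 fold change 2.03 ± 0.37 (SE), limma BH-adjusted p = 0.00737.

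6D7 at 48 h also shifted glycolysis and lysosome lists up and cell division lists down. Lysosome genes had a median log2 fold change 1.21 over 45 members, 0.88 after median-of-ratios scaling, camera BH-adjusted p = 4.2e-17, adjusted p = 0.211 with an estimated correlation. The list had 32 members called higher, 0 lower and 13 not called, with 38 higher and 0 lower adjusted over the list alone. CTSB, a lysosomal protease, rose from 146 ± 28.9 to 487 ± 29.5 TPM (SD, n = 2), log2 fold change 1.74 ± 0.18 (SE), limma BH-adjusted p = 0.000464. Glycolysis genes had a median log2 fold change 1.48 over 35 members, 1.16 after median-of-ratios scaling, camera BH-adjusted p = 2.9e-11, adjusted p = 0.215 with an estimated correlation. The list had 19 members called higher, 0 lower and 16 not called, with 26 higher and 0 lower adjusted over the list alone, and ALDOC and HK2 were called by limma with BH adjustment as ALDOC (10.1 ± 5.47 to 166 ± 91.0, log2 3.89, adjusted p = 0.00280) and HK2 (1.29 ± 0.850 to 23.7 ± 11.2, log2 3.40, adjusted p = 0.000750). DNA replication genes had a median log2 fold change -1.73 over 39 members, -1.97 after median-of-ratios scaling, camera BH-adjusted p = 2.1e-43, adjusted p = 0.215 with an estimated correlation. The list had 29 members called lower, 0 higher and 10 not called, with 38 lower and 0 higher adjusted over the list alone, with MCM5 down from 61.0 ± 6.70 to 10.3 ± 7.91 TPM (SD, n = 2), log2 fold change -2.66 ± 0.39 (SE), limma BH-adjusted p = 0.00290. Mitotic genes had a median log2 fold change -1.93 over 30 members, -2.21 after median-of-ratios scaling, camera BH-adjusted p = 4.4e-26, adjusted p = 0.215 with an estimated correlation. The list had 9 members called lower, 0 higher and 21 not called, with 25 lower and 0 higher adjusted over the list alone, and their median was -1.07 without 6D7 replicate 1 and -2.93 without 6D7 replicate 2. KIF18B, a mitotic kinesin, CDC45, a helicase subunit, PKMYT1, a kinase that holds CDK1 in check, and AURKB, a kinase of chromosome segregation, were called by limma with BH adjustment as KIF18B (34.4 ± 3.78 to 5.51 ± 6.34, log2 -2.90, adjusted p = 0.0159), CDC45 (28.6 ± 4.88 to 4.17 ± 4.52, log2 -2.85, adjusted p = 0.0186), PKMYT1 (41.4 ± 14.4 to 7.48 ± 8.69, log2 -2.82, adjusted p = 0.0254) and AURKB (85.6 ± 12.2 to 15.5 ± 15.7, log2 -2.82, adjusted p = 0.0303). IGFBP1 rose from 63.5 ± 50.5 to 1160.5 ± 535 TPM (SD, n = 2), log2 fold change 4.35 ± 0.48 (SE), limma BH-adjusted p = 0.000750, IGFL2-AS1 from 3.34 ± 0.954 to 142 ± 79.7 TPM (SD, n = 2), log2 fold change 4.93 ± 0.64 (SE), limma BH-adjusted p = 0.00171, and the MIR6783 stretch of KIF18B fell from 16.8 ± 6.45 to 1.95 ± 2.76 TPM (SD, n = 2), log2 fold change -2.96 ± 0.57 (SE), limma BH-adjusted p = 0.00929. Ribosome biogenesis genes had a median log2 fold change -0.35 over 35 members, -0.67 after median-of-ratios scaling, camera BH-adjusted p = 3.9e-12, adjusted p = 0.215 with an estimated correlation. The list had 3 members called lower, 0 higher and 32 not called, with 2 lower and 0 higher adjusted over the list alone. TRNC and TRNY were called through the listing at 0 described above, and RNF113A through its 0 in DMSO.

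Exosome genes shifted upward with 6D7 at 48 h, and the size depended on scaling. The exosome list had a median log2 fold change 0.64 over 64 members, 0.32 after median-of-ratios scaling, camera BH-adjusted p = 1.7e-06, adjusted p = 0.215 with an estimated correlation. The list had 22 members called higher, 0 lower and 42 not called, with 30 higher and 0 lower adjusted over the list alone. After median-of-ratios scaling 4 members were called higher. SDCBP rose from 125 ± 24.7 to 449.9 ± 1.63 TPM (SD, n = 2), log2 fold change 1.85 ± 0.28 (SE), limma BH-adjusted p = 0.00365. STX4, a SNARE of membrane fusion, rose from 47.4 ± 0.0718 to 125 ± 37.97 TPM (SD, n = 2), log2 fold change 1.35 ± 0.24 (SE), limma BH-adjusted p = 0.00726, and its limma BH-adjusted p was 0.0525 after median-of-ratios scaling. CD63 rose on TPM from 1386 ± 103 to 2305 ± 368 TPM (SD, n = 2), log2 fold change 0.73 ± 0.21 (SE), limma BH-adjusted p = 0.0393, against log2 0.40 and a limma BH-adjusted p of 0.373 after median-of-ratios scaling. AMPK genes were not called as a list (median log2 fold change 0.39 over 20 members, 0.07 after median-of-ratios scaling, camera BH-adjusted p = 0.354, adjusted p = 0.715 with an estimated correlation). This list had 2 members called higher, 0 lower and 18 not called, with 4 higher and 0 lower adjusted over the list alone. PRKAA1 had log2 -0.11 (limma BH-adjusted p = 0.839). NF-kB genes lay higher (median log2 fold change 1.38 over 25 members, 1.06 after median-of-ratios scaling, camera BH-adjusted p = 0.000327, adjusted p = 0.561 with an estimated correlation). This list had 7 members called higher, 0 lower and 18 not called, with 14 higher and 0 lower adjusted over the list alone. Without 6D7 replicate 1 the NF-kB median was 0.80 and camera did not call the list. Without DMSO replicate 1, DMSO replicate 2, 6D7 replicate 1 or 6D7 replicate 2, limma called 169, 999, 481 and 2321 genes. Of the 56 named calls, 22, 38, 31 and 51 were called again, and 46 were after median-of-ratios scaling.

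7F8 at 48 h shifted the NF-kB list up, as did 5G6 (library medians 1.33 and 0.79 after median-of-ratios scaling), and cell division lists down. With 7F8 NF-kB genes had a median log2 fold change 1.42 over 25 members, 1.67 after median-of-ratios scaling, camera BH-adjusted p = 6.1e-18, adjusted p = 0.187 with an estimated correlation. The list had 10 members called higher, 0 lower and 15 not called, with 15 higher and 0 lower adjusted over the list alone. SOD2 rose from 144 ± 19.5 to 1917 ± 456 TPM (SD, n = 2), log2 fold change 3.71 ± 0.29 (SE), limma BH-adjusted p = 0.000226. IL6, an inflammatory cytokine, rose from 10.2 ± 0.787 to 123 ± 80.1 TPM (SD, n = 2), log2 fold change 3.30 ± 0.41 (SE), limma BH-adjusted p = 0.00267. PI3, the protease inhibitor elafin, and C15orf48, a small mitochondrial protein induced in inflammation, were called by limma with BH adjustment as PI3 (6.83 ± 0.654 to 168 ± 125, log2 4.20, adjusted p = 0.00326) and C15orf48 (32.9 ± 12.9 to 552 ± 90.7, log2 4.07, adjusted p = 0.00226). SAA1 and SAA2, acute-phase proteins whose near-identical genes share reads, were called by limma with BH adjustment as SAA1 (5.98 ± 5.33 to 149 ± 169, log2 3.94, adjusted p = 0.0275) and SAA2 (2.63 ± 1.72 to 78.4 ± 81.4, log2 4.00, adjusted p = 0.0104). Mitotic genes had a median log2 fold change -2.72 over 30 members, -2.51 after median-of-ratios scaling, camera BH-adjusted p = 2.5e-15, adjusted p = 0.363 with an estimated correlation. The list had 23 members called lower, 0 higher and 7 not called, with 30 lower and 0 higher adjusted over the list alone, and DNA replication genes had a median log2 fold change -2.30 over 39 members, -2.06 after median-of-ratios scaling, camera BH-adjusted p = 3.6e-26, adjusted p = 0.293 with an estimated correlation. The list had 36 members called lower, 0 higher and 3 not called, with 38 lower and 0 higher adjusted over the list alone. KIF18B and RRM2, a subunit of the enzyme that makes deoxynucleotides, were called by limma with BH adjustment as KIF18B (34.4 ± 3.78 to 2.54 ± 2.01, log2 -3.45, adjusted p = 0.0115) and RRM2 (110.5 ± 29.2 to 10.5 ± 9.17, log2 -3.52, adjusted p = 0.0172). AURKA, a kinase of the mitotic spindle, fell from 93.2 ± 0.703 to 14.9 ± 6.93 TPM (SD, n = 2), log2 fold change -2.64 ± 0.45 (SE), limma BH-adjusted p = 0.00900. Without DMSO replicate 1, DMSO replicate 2, 7F8 replicate 1 or 7F8 replicate 2, limma called 34, 297, 43 and 875 genes. Of the 47 named calls, 9, 24, 11 and 37 were called again, and 45 were after median-of-ratios scaling.

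The epithelial list shifted down with 7F8 at 48 h and the lysosome list up. Epithelial markers had a median log2 fold change -1.16 over 12 members, -0.91 after median-of-ratios scaling, camera BH-adjusted p = 0.0207, adjusted p = 0.293 with an estimated correlation. The list had 3 members called lower, 0 higher and 9 not called, with 4 lower and 0 higher adjusted over the list alone. MUC5AC, an airway mucin, fell from 61.1 ± 4.27 to 6.74 ± 0.247 TPM (SD, n = 2), log2 -3.00 ± 0.61 (SE), limma BH-adjusted p = 0.0155. EPCAM, an epithelial adhesion protein, fell (5.44 ± 0.180 to 0.401 ± 0.208, log2 -2.21, limma BH-adjusted p = 0.0129). SPDEF, a factor for mucus-producing cells, and the membrane proteins TM4SF4 and TM4SF20 were called by limma with BH adjustment as SPDEF (20.6 ± 8.04 to 0.683 ± 0.789, log2 -3.71, adjusted p = 0.0102), TM4SF4 (79.5 ± 16.3 to 4.09 ± 2.46, log2 -4.06, adjusted p = 0.0119) and TM4SF20 (45.3 ± 1.24 to 2.90 ± 0.424, log2 -3.57, adjusted p = 0.0236). So was the MIR6783 stretch of KIF18B (16.8 ± 6.45 to 0.0945 ± 0.134, log2 -3.98, adjusted p = 0.00473). With 5G6 and 6D7 EPCAM and TM4SF4 lay below DMSO too, and SPDEF, MUC5AC and TM4SF20 in some libraries. Lysosome genes had a median log2 fold change 0.73 over 45 members, 0.98 after median-of-ratios scaling, camera BH-adjusted p = 2.6e-23, adjusted p = 0.0868 with an estimated correlation. The list had 19 members called higher, 0 lower and 26 not called, with 28 higher and 0 lower adjusted over the list alone. NEU1, a lysosomal sialidase listed at 8 places in the files, rose from 18.8 ± 0.543 to 107 ± 25.7 TPM (SD, n = 2), log2 fold change 2.43 ± 0.21 (SE), limma BH-adjusted p = 0.000339. SQSTM1 rose from 486 ± 5.73 to 1943 ± 199 TPM (SD, n = 2), log2 fold change 1.99 ± 0.27 (SE), limma BH-adjusted p = 0.00367. Ribosome biogenesis genes had a median log2 fold change -0.93 over 35 members, -0.69 after median-of-ratios scaling, camera BH-adjusted p = 3.9e-14, adjusted p = 0.210 with an estimated correlation. The list had 20 members called lower, 0 higher and 15 not called, with 33 lower and 0 higher adjusted over the list alone.

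Sterol genes answered 7F8 at 48 h in 1 of its 2 libraries. The sterol list was called (median log2 fold change 0.70 over 26 members, 0.94 after median-of-ratios scaling, camera BH-adjusted p = 3.0e-07, adjusted p = 0.435 with an estimated correlation). This list had 1 member called higher, 0 lower and 25 not called, with 1 higher and 0 lower adjusted over the list alone. Its median was 0.01 without 7F8 replicate 1, where camera did not call the list, and 1.40 without 7F8 replicate 2. LSS rose from 21.4 ± 1.38 to 76.6 ± 46.0 TPM (SD, n = 2), log2 fold change 1.65 ± 0.39 (SE), limma BH-adjusted p = 0.0257. INSIG1 had 24.7 ± 2.78 and 88.1 ± 68.9 TPM (SD, n = 2) (log2 1.54, limma BH-adjusted p = 0.126). The exosome list had a negative median and a positive mean of 0.03, and was called upward (median log2 fold change -0.07 over 64 members, 0.17 after median-of-ratios scaling, camera BH-adjusted p = 0.0171, adjusted p = 0.435 with an estimated correlation). This list had 3 members called higher, 1 lower and 60 not called, with 3 higher and 1 lower adjusted over the list alone. CD82, a tetraspanin found on exosomes, and SDCBP rose, called by limma with BH adjustment as CD82 (2.06 ± 0.807 to 12.9 ± 7.02, log2 2.11, adjusted p = 0.0160) and SDCBP (125 ± 24.7 to 335 ± 27.2, log2 1.43, adjusted p = 0.0140), each ± SD (n = 2). CD63 had log2 -0.25 (limma BH-adjusted p = 0.489). AMPK genes were not called as a list (median log2 fold change -0.18 over 20 members, 0.06 after median-of-ratios scaling, camera BH-adjusted p = 0.973, adjusted p = 0.981 with an estimated correlation). This list had 0 of 20 members called by limma, with 0 higher and 0 lower adjusted over the list alone.

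**Figure D4:**
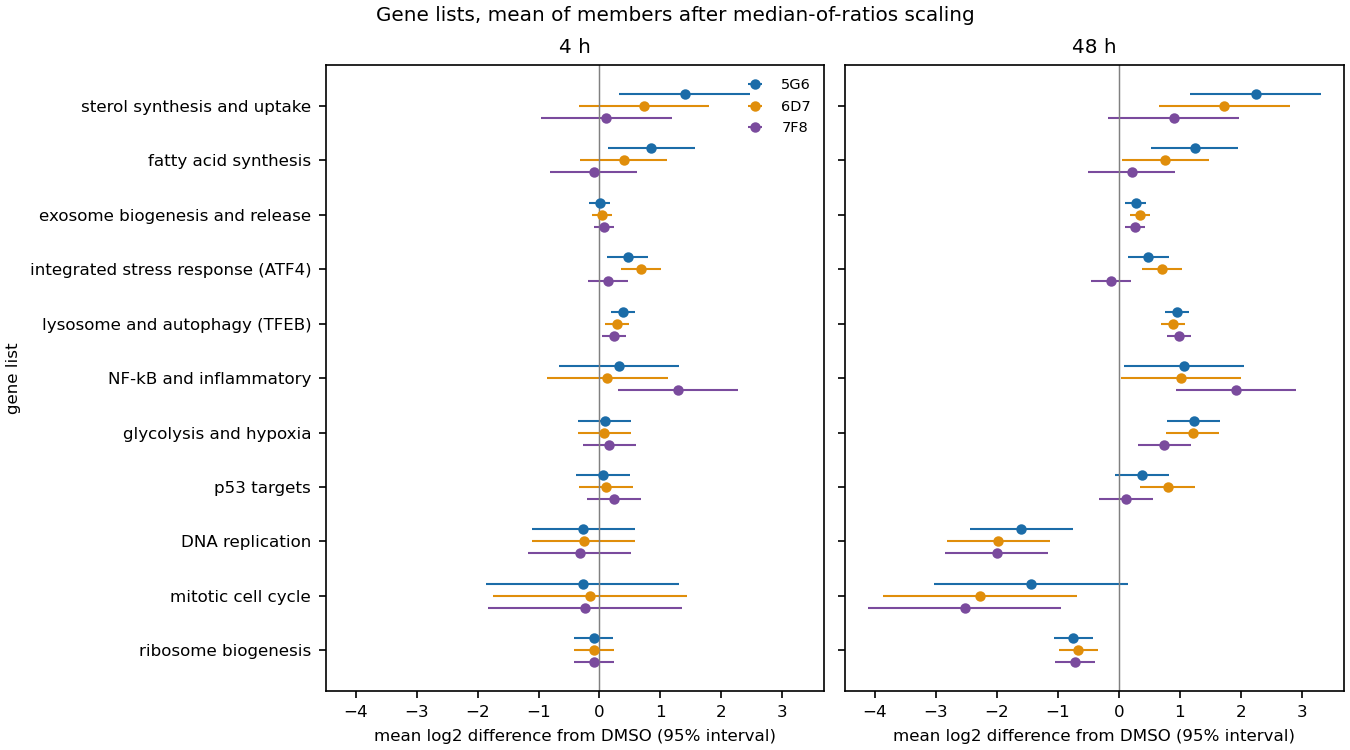
Mean log2 difference from DMSO of 11 gene lists for each compound at 4 h and 48 h after median-of-ratios scaling, with 95% intervals.

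At 4 h some list intervals between compounds left out 0, with no replicate block. Of 156 list tests between compounds at both times, camera called 76, and 0 with an estimated correlation. After median-of-ratios scaling the mean sterol difference was 1.28 (95% interval 0.21 to 2.36) for 5G6 minus 7F8, 0.66 (95% interval -0.41 to 1.74) for 5G6 minus 6D7 and 0.62 (95% interval -0.45 to 1.69) for 6D7 minus 7F8. The ATF4 difference was 0.55 (95% interval 0.22 to 0.88) for 6D7 minus 7F8. For NF-kB genes it was -0.97 (95% interval -1.96 to 0.02) for 5G6 minus 7F8 and -1.16 (95% interval -2.15 to -0.18) for 6D7 minus 7F8. Limma called 2 genes between 5G6 and 7F8. ELOVL6, which lengthens palmitate, was higher with 5G6 than with 7F8, from 4.15 ± 1.37 to 29.5 ± 1.77 TPM (SD, n = 2), log2 fold change 2.59 ± 0.31 (SE), limma BH-adjusted p = 0.0345. UAP1L1 was higher with 5G6 as well, from 5.78 ± 2.84 to 30.4 ± 2.35 TPM (SD, n = 2), log2 fold change 2.28 ± 0.29 (SE), limma BH-adjusted p = 0.0376, with a limma BH-adjusted p of 0.0870 after median-of-ratios scaling. Without 5G6 replicate 1, 5G6 replicate 2, 7F8 replicate 1 or 7F8 replicate 2, 0, 0, 2 and 1 of these 2 calls held. Limma called 0 genes between 5G6 and 6D7 and 0 between 6D7 and 7F8, with 177 (below chance) and 935 at an unadjusted p below 0.05.

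At 48 h few genes separated 5G6 from 6D7, and the intervals of both against 7F8 left out 0 for epithelial and ATF4 genes. Mean sterol difference after median-of-ratios scaling was 1.35 (95% interval 0.28 to 2.42) for 5G6 minus 7F8, 0.52 (95% interval -0.56 to 1.59) for 5G6 minus 6D7 and 0.83 (95% interval -0.24 to 1.91) for 6D7 minus 7F8. ATF4 genes differed by 0.61 (95% interval 0.28 to 0.94) for 5G6 minus 7F8 and 0.83 (95% interval 0.50 to 1.16) for 6D7 minus 7F8. Epithelial markers differed by 0.99 (95% interval 0.51 to 1.47) and 0.76 (95% interval 0.28 to 1.24) for these pairs. The p53 targets differed by 0.68 (95% interval 0.23 to 1.12) for 6D7 minus 7F8, and NF-kB genes by -0.85 (95% interval -1.84 to 0.13) for 5G6 minus 7F8. Exosome genes differed by -0.08 (95% interval -0.25 to 0.09) for 5G6 minus 6D7 and 0.00 (95% interval -0.16 to 0.17) for 5G6 minus 7F8. KRT19, an epithelial keratin, was higher with 5G6 than with 7F8, from 19.4 ± 11.4 to 239.5 ± 58.9 TPM (SD, n = 2), log2 fold change 3.66 ± 0.51 (SE), limma BH-adjusted p = 0.0263. It was higher with 6D7 than with 7F8 too, from 19.4 ± 11.4 to 288 ± 57.9 TPM (SD, n = 2), log2 fold change 3.93 ± 0.51 (SE), limma BH-adjusted p = 0.00326. FXYD2, a regulator of the sodium pump, and CA9, a carbonic anhydrase of hypoxia, were higher with 5G6 than with 7F8, by limma with BH adjustment FXYD2 (20.4 ± 4.24 to 444 ± 297, log2 4.21, adjusted p = 0.0306) and CA9 (4.71 ± 2.25 to 67.8 ± 15.4, log2 3.63, adjusted p = 0.0455). After median-of-ratios scaling the limma BH-adjusted p was 0.0539 for FXYD2 and 0.0449 for CA9. EFNA1, an ephrin ligand under NF-kB, was lower with 6D7 than with 7F8, from 535 ± 119.9 to 85.5 ± 4.52 TPM (SD, n = 2), log2 fold change -2.61 ± 0.44 (SE), limma BH-adjusted p = 0.00848.

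Counts against 7F8 at 48 h depended on scaling. Limma called 3 genes between 5G6 and 6D7 under both scalings, namely TRNC, TRNY and the read-through gene ISY1-RAB43, which was listed at 0 in both 5G6 libraries and at 10.9 and 8.79 TPM with 6D7. Between 5G6 and 7F8 it called 52 genes, and 19 after median-of-ratios scaling. Between 6D7 and 7F8 it called 2518 genes (2487 higher), and 76 (54 higher) after median-of-ratios scaling. All-gene medians were -0.36, 0.13 and 0.50 for these pairs on TPM. Without 5G6 replicate 1, 5G6 replicate 2, 7F8 replicate 1 or 7F8 replicate 2, 0, 0, 0 and 2 of the 8 named calls between 5G6 and 7F8 held, KRT19, FXYD2 and CA9 among the 8. After median-of-ratios scaling 4 of these 8 held. Without 6D7 replicate 1, 6D7 replicate 2, 7F8 replicate 1 or 7F8 replicate 2, 5, 6, 4 and 6 of the 8 named calls between 6D7 and 7F8 held, and 5 after median-of-ratios scaling. Leaving out 6D7 replicate 2, limma called 639 genes between 5G6 and 6D7.

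The 3 compounds shared many changed genes at 48 h, with some replication genes down and some lysosome genes up. Log2 fold changes correlated at r = 0.82 for 5G6 and 6D7, 0.76 for 5G6 and 7F8 and 0.70 for 6D7 and 7F8, against a simulated r of 0.50 from the shared DMSO libraries alone. Covariances were 0.329, 0.298 and 0.316, against 0.068 simulated. Genes called higher in both numbered 274, 102 and 217, where 31.2, 5.95 and 34.7 were expected of independent lists. Genes called lower in both numbered 99, 215 and 207, where 3.52, 14.8 and 14.9 were expected, and 0, 0 and 3 were called in opposite directions. After median-of-ratios scaling 285, 190 and 198 were higher in both (13.0, 14.6 and 18.6 expected) and 194, 174 and 338 lower in both (7.57, 9.26 and 20.4 expected). Part of the excess may come from the shared DMSO libraries, which at n = 2 cannot be split. All 3 compounds called 102 genes higher and 97 lower, 158 and 153 after median-of-ratios scaling. These included 21 of 39 DNA replication genes lower and 15 of 45 lysosome genes higher.

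The effects of 5G6, 6D7 and 7F8 differed between 48 h and 4 h in few single genes and in 40 of 78 list tests, of which 0 were called with an estimated correlation. Limma called 0 genes for 5G6 (1150 at an unadjusted p below 0.05), 6 for 6D7 and 1 for 7F8, and 0, 5 and 2 after median-of-ratios scaling. With a replicate block the calls were 0, 11 and 93. DDC had a lower effect at 48 h with 6D7, by a log2 difference of -2.03, and with 7F8, -2.33 (limma BH-adjusted p = 0.0325 and 0.0494). Leaving out 1 library lost the DDC call in 7 of 8 fits for each compound. DDC stood lower at 48 h with 5G6 too (0.715 and 0.636 TPM, 4.70 and 4.50 at 4 h), without a called time difference. CDA, a cytidine deaminase, had a larger effect of 6D7 at 48 h by 2.45 (limma BH-adjusted p = 0.0325, 0.278 after median-of-ratios scaling). Leaving out 1 library gave 2 to 313 calls for 6D7, the most without 6D7 replicate 2 of 48 h, and 0 to 21 for 7F8, the most without 7F8 replicate 2 of 48 h. DNA replication genes moved further down at 48 h with 5G6 (median log2 fold change -1.62 over 39 members, -1.38 after median-of-ratios scaling, camera BH-adjusted p = 2.2e-22, adjusted p = 0.366 with an estimated correlation). This list had 0 of 39 members called by limma, with 0 higher and 29 lower adjusted over the list alone. Sterol genes moved further up with 6D7 (median log2 fold change 1.28 over 26 members, 1.01 after median-of-ratios scaling, camera BH-adjusted p = 1.7e-07, adjusted p = 0.544 with an estimated correlation). This list had 0 of 26 members called by limma, with 0 higher and 0 lower adjusted over the list alone. In DMSO alone limma called 0 genes between 48 h and 4 h, with 250 (574 with the block) at an unadjusted p below 0.05. Ribosomal protein genes were lower at 48 h in DMSO (median log2 fold change -0.26 over 40 members, -0.35 after median-of-ratios scaling, camera BH-adjusted p = 5.1e-20, adjusted p = 0.617 with an estimated correlation). This list had 0 of 40 members called by limma, with 0 higher and 0 lower adjusted over the list alone.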

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

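The tests of the 2 patterns at the end of this part were chosen or given their bounds after the results were seen. Each result listed here differed between 48 h and 4 h by a test of the difference itself. That test asked whether the effect of a compound against DMSO was larger or smaller at the later time. None of the list calls among them held with an estimated correlation, where adjusted p ran from 0.208 to 0.818.

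5G6 shifted growth and glycolysis genes further at 48 h than at 4 h. Medians of the log2 difference over lists called by camera with BH adjustment, here and below with the median after median-of-ratios scaling in parentheses, were -1.62 (-1.38) for DNA replication, -1.36 (-1.10) for mitotic cell cycle, -0.88 (-0.63) for ribosome biogenesis and -0.85 (-0.60) for heat shock response. They were 0.93 (1.08) for glycolysis and hypoxia, 0.59 (0.84) for sterol synthesis and uptake, 0.57 (0.76) for replication-dependent histones, 0.52 (0.75) for interferon response, 0.50 (0.75) for NF-kB, 0.32 (0.57) for lysosome and autophagy and 0.0912 (0.34) for fatty acid synthesis. Exosome genes at -0.0214 (0.22) and p53 targets at -0.0340 (0.18) had TPM medians below 0 while the test called them upward.

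6D7 had time differences in single genes and in lists. Limma called 6 genes with BH adjustment: TRNC (log2 difference -17.79), TRNY (12.38), ISY1-RAB43 (3.04), CDA (2.45), DDC (-2.03) and KCP (2.36), a secreted regulator of bone morphogenetic protein signalling named here after its value was seen because it fell outside the naming rule. TRNC, TRNY and ISY1-RAB43 were listed at 0 in at least 1 of the groups compared, so these 3 differences have no meaningful size. List medians called by camera with BH adjustment were -1.82 (-2.06) for mitotic cell cycle, -1.57 (-1.80) for DNA replication, -0.31 (-0.58) for ribosome biogenesis and -0.14 (-0.41) for NRF2 targets. Upward medians were 1.31 (1.04) for glycolysis and hypoxia, 1.28 (1.01) for sterol synthesis and uptake, 1.10 (0.83) for NF-kB, 0.99 (0.79) for replication-dependent histones, 0.82 (0.57) for p53 targets, 0.82 (0.55) for lysosome and autophagy, 0.52 (0.27) for exosome genes and 0.43 (0.16) for ribosomal proteins, which camera did not call after scaling.

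7F8 had 1 gene with a time difference, DDC (-2.33), called by limma with BH adjustment. List medians called by camera with BH adjustment were -2.44 (-2.31) for mitotic cell cycle, -1.77 (-1.66) for DNA replication, -0.79 (-0.63) for ribosome biogenesis, -0.69 (-0.53) for epithelial markers, -0.59 (-0.44) for NRF2 targets, -0.42 (-0.28) for ATF4 genes and -0.30 (-0.15) for oxidative phosphorylation. Upward medians were 1.12 (1.28) for interferon response, 0.70 (0.86) for sterol synthesis and uptake, 0.57 (0.73) for lysosome and autophagy, 0.48 (0.64) for glycolysis and hypoxia, 0.38 (0.54) for endoplasmic reticulum chaperones, 0.29 (0.44) for NF-kB, 0.27 (0.43) for TGF-beta and mesenchymal genes and 0.0703 (0.23) for ribosomal proteins. Single libraries carried some of these: without 7F8 replicate 1 of 48 h the sterol median was -0.01.

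Many more genes were called higher than lower with 6D7 at 48 h, 87.7 percent of the calls. With TPM recomputed without TRNC and TRNY 40.92 percent were higher, and without all mitochondrial genes 39.46 percent. The excess was gone in both, as a TPM scale moved by these genes predicts. A loss of RNA from the TRNC and TRNY locus as a whole was excluded, because the summed coverage of both genes per aligned gigabase in the lower 6D7 library was 147.1 percent of the lowest other library. A change from TRNC to TRNY within the locus, in the RNA or in the assignment of reads, was not tested.

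Sterol genes were high in 1 of the 2 libraries of 7F8 at 48 h, with medians of 1.73 and 0.18 against DMSO after median-of-ratios scaling. A 5G6 or 6D7 library under the 7F8 label was excluded: at 71 percent of 200 genes that set the other 7F8 library apart from 5G6 and 6D7, the library lay nearer the other 7F8 library. The 5G6 and 6D7 libraries, each left out in turn, did so at 4.5 to 31.5 percent. A mixed library was not tested. A shift of every replicate 1 library was excluded, since the sterol list differed by 0.1461 between the DMSO libraries. A stronger response of every gene was not tested. The difference between the 2 libraries has no tested cause.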

How the results depend on the processing

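TPM recomputed without mitochondrial genes, the replicate block with median-of-ratios scaling and the leave-one-out counts after median-of-ratios scaling were chosen after the results were seen; all other alternatives were set before. Groups of 2 libraries limit every result here. Of the gene list results outside the sterol, fatty acid and exosome lists, 5033 values over all alternatives held their direction and side of the threshold, 478 lost the call, 213 gained it and 56 changed direction. For sterol, fatty acid and exosome lists against DMSO the numbers were 232, 16, 4 and 0. For named genes 4343 values held, 632 lost the call and 79 gained it. Genes near the filter carry few reads, and depth of 6.10 to 8.86 aligned gigabases limits them. Where a cause is not given in the setting itself, the cause was not tested.

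With FPKM the calls were 1013 for 6D7 against DMSO at 48 h, 29 for 5G6 against 7F8 and 76 for 6D7 against 7F8 at 48 h, and 2 for the 7F8 time difference. Median-of-ratios scaling gave 1008, 19, 76 and 2 for these, and 1 for 5G6 against 7F8 at 4 h. TPM without mitochondrial genes gave 958 for 6D7 against DMSO and 73 against 7F8 at 48 h, 1 for 5G6 against 6D7 at 48 h and 1 against 7F8 at 4 h. It gave 0 for 5G6 against DMSO at 4 h and 0 for the 6D7 time difference. Nuclear oxidative phosphorylation genes changed direction with scaling. For 6D7 against DMSO at 48 h their median was 0.20 on TPM, -0.19 with FPKM, -0.12 after median-of-ratios scaling and -0.21 without mitochondrial genes. For 5G6 against 6D7 at 48 h it was -0.38 on TPM and 0.0156, 0.0469 and 0.0344 under the other 3.

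With no filter on low values the calls were 22, 2 and 7 for 5G6, 6D7 and 7F8 against DMSO at 4 h. They were 10, 18 and 5 for 5G6 against 6D7, 5G6 against 7F8 and 6D7 against 7F8 at 4 h, and 58 for 5G6 against 6D7 at 48 h. Time differences had 11, 36 and 7 calls for 5G6, 6D7 and 7F8, and DMSO time had 6. The median log2 fold change of exosome biogenesis and release, 6D7 against DMSO at 4 h, was then 0.0923 and called, and that for 7F8 at 48 h was -0.0613 and not called. With a pseudocount of 0.1 the calls were 1, 1, 1, 5, 1 and 2 for 6D7 and 7F8 against DMSO, 5G6 against 6D7, 5G6 against 7F8 and 6D7 against 7F8 at 4 h, and the 6D7 time difference. Variance without the trend gave 0 calls for 5G6 at 4 h.

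With the 8 libraries of 1 time point alone, and so fewer degrees of freedom, 0 genes were called for 5G6 at 4 h and 8, 403 and 169 for 5G6, 6D7 and 7F8 at 48 h. Between compounds these fits gave 1, 0 and 1 at 4 h for 5G6 against 6D7, 5G6 against 7F8 and 6D7 against 7F8. At 48 h they gave 1 for 5G6 against 7F8 and 104 for 6D7 against 7F8. An estimated correlation took the call from 12 of the 18 sterol, fatty acid and exosome results. Their medians were 1.59, 0.84, 2.23, 2.08 and 0.70 for sterol genes, 0.82, 0.33, 0.88 and 1.14 for fatty acid genes and 0.10, 0.64 and -0.0717 for exosome genes.

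A replicate block asks whether libraries of the same number share a shift. The labels give no pairing, but all 16 libraries were closest to one of their own number. Replicate differences correlated at 0.383 to 0.630 within a time point and 0.058 to 0.358 across times (28 pairs). That is a hint from the data alone. The block called 7, 1739, 3806 and 2944 genes for 5G6 at 4 h and 5G6, 6D7 and 7F8 at 48 h. It gave 7 and 230 for 5G6 against 7F8 at 4 h and 48 h, 5542 for 6D7 against 7F8 at 48 h, and 11 and 93 for the 6D7 and 7F8 time differences. With the replicate block and median-of-ratios scaling 1654 and 2401 were called for 5G6 and 7F8 at 48 h. The same fit gave 0 and 165 for 5G6 against 7F8 at 4 h and 48 h, 302 for 6D7 against 7F8 at 48 h and 57 for the 7F8 time difference. The replicate block called exosome genes for 6D7 at 4 h (median 0.10). Its test turned direction for interferon genes in 5G6 against 7F8 at 4 h (0.48, and 0.29 with median-of-ratios scaling) and in the 6D7 time difference (0.54 and 0.32). Oxidative phosphorylation in 5G6 against 6D7 at 48 h was 0.0469 under the block with median-of-ratios scaling.

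Leaving out each library in turn leaves a group with 1 library, which is assumed to vary like the other groups. Lowest and highest calls were 0 and 2, 0 and 1, and 0 and 19 for 5G6, 6D7 and 7F8 at 4 h. At 48 h they were 5 and 122, 169 and 2321, and 34 and 875, and after median-of-ratios scaling 6 and 228, 40 and 1779, and 69 and 890. Between compounds they were 0 and 2, 1 and 32, and 0 and 15 at 4 h, and 3 and 639, 1 and 17, and 89 and 2016 at 48 h. For time differences they were 0 and 2, 2 and 313, and 0 and 21, and for DMSO time 0 and 1. List medians given next, lowest and highest, belong to lists whose test turned direction or, for sterol, fatty acid and exosome genes, changed its call. For 5G6 against DMSO at 4 h they were -0.21 and 0.47 for heat shock response and -0.68 and 0.65 for interferon response. In 6D7 against DMSO at 4 h these were 0.18 and 0.53 for fatty acid synthesis, 0.0617 and 0.17 for exosome biogenesis and release, -0.0333 and 0.50 for endoplasmic reticulum chaperones and -0.46 and 0.25 for mitotic cell cycle. 6D7 against DMSO at 4 h gave -0.48 and 0.0626 for DNA replication, -0.66 and 0.58 for interferon response and -0.36 and 0.37 for TGF-beta and mesenchymal. For 7F8 against DMSO at 4 h they were -0.12 and 0.22 for ribosomal proteins. In 5G6 against DMSO at 48 h these were -0.32 and 1.13 for interferon response. 6D7 against DMSO at 48 h gave 0.91 and 1.31 for fatty acid synthesis. For 7F8 against DMSO at 48 h they were 0.0109 and 1.40 for sterol synthesis and uptake and -0.21 and 0.24 for fatty acid synthesis. In 5G6 against 6D7 at 4 h these were -0.24 and 0.21 for endoplasmic reticulum chaperones, -0.46 and 0.36 for mitotic cell cycle, -0.24 and 0.34 for DNA replication and 0.00932 and 0.69 for heat shock response. 5G6 against 6D7 at 4 h gave -0.81 and 0.20 for metallothioneins, -0.61 and 0.63 for interferon response, -0.25 and 0.94 for immediate early genes and -0.14 and 0.30 for ribosome biogenesis. For 5G6 against 7F8 at 4 h they were -0.0767 and 0.60 for DNA replication, -0.0802 and 1.19 for interferon response and -0.37 and 0.92 for immediate early genes. In 6D7 against 7F8 at 4 h these were 0.0144 and 0.62 for endoplasmic reticulum chaperones, -0.14 and 0.54 for DNA replication, -0.19 and 1.11 for interferon response and -0.23 and 0.13 for ribosomal proteins. 5G6 against 6D7 at 48 h gave -0.74 and 0.70 for LXR targets, -0.51 and 0.52 for DNA replication, -0.58 and 0.0411 for NRF2 targets and -0.55 and 0.18 for replication-dependent histones. For 5G6 against 7F8 at 48 h they were -0.90 and 0.64 for interferon response. In 6D7 against 7F8 at 48 h these were -0.64 and 0.87 for LXR targets, -0.14 and 1.73 for mitotic cell cycle, -0.0556 and 0.92 for DNA replication and 0.14 and 0.72 for NRF2 targets. 6D7 against 7F8 at 48 h gave 0.17 and 0.42 for ribosomal proteins. For the 7F8 time difference they were -0.00705 and 1.54 for sterol synthesis and uptake and -0.10 and 0.25 for ribosomal proteins. In DMSO at 48 h against DMSO at 4 h these were -0.27 and 0.92 for interferon response.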

Other observations

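The lists were written in advance, but those described here and the looks library by library were chosen after the results were seen. Replication-dependent histones, in polyA RNA, stood higher with 7F8 at 48 h (median log2 fold change 0.65 over 14 members, 0.87 after median-of-ratios scaling, camera BH-adjusted p = 5.6e-05, adjusted p = 0.293 with an estimated correlation). They had 3 members called higher, 0 lower and 11 not called, with 4 higher and 0 lower adjusted over the list alone, and their median was 0.32 without DMSO replicate 1. At 4 h with 7F8 they were higher as well (median log2 fold change 0.86 over 14 members, 0.96 after median-of-ratios scaling, camera BH-adjusted p = 1.2e-09, adjusted p = 0.164 with an estimated correlation). These had 0 of 14 members called by limma, with 1 higher and 0 lower adjusted over the list alone, with medians of 1.42 and 0.32 without 7F8 replicate 1 and replicate 2. With 5G6 the 48 h library medians were 0.62 and 0.64, and with 6D7 1.19 and 0.62.

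Mesenchymal genes under TGF-beta were higher with 7F8 at 48 h (median log2 fold change 0.27 over 22 members, 0.51 after median-of-ratios scaling, camera BH-adjusted p = 0.00255, adjusted p = 0.293 with an estimated correlation). Among them were 2 members called higher, 1 lower and 19 not called, with 2 higher and 1 lower adjusted over the list alone, and camera did not call the list without DMSO replicate 2 (median 0.18). ITGB3, an integrin subunit, rose from 0.984 ± 0.150 to 13.9 ± 4.74 TPM (SD, n = 2), log2 fold change 2.87 ± 0.30 (SE), limma BH-adjusted p = 0.00173. Nuclear genes of oxidative phosphorylation were lower with 7F8 at 48 h (median log2 fold change -0.39 over 39 members, -0.14 after median-of-ratios scaling, camera BH-adjusted p = 0.000123, adjusted p = 0.512 with an estimated correlation). They had 6 members called lower, 0 higher and 33 not called, with 10 lower and 0 higher adjusted over the list alone, and their median was -0.21 without 7F8 replicate 1. Endoplasmic reticulum chaperones stood higher as a list with 5G6 at 48 h (median log2 fold change 0.21 over 26 members, 0.32 after median-of-ratios scaling, camera BH-adjusted p = 0.00383, adjusted p = 0.623 with an estimated correlation). They had 0 of 26 members called by limma, with 0 higher and 0 lower adjusted over the list alone, and their median ran from 0.13 without DMSO replicate 1 to 0.43 without DMSO replicate 2. Immediate early genes stood higher as a list with 5G6 at 48 h (median log2 fold change 0.49 over 28 members, 0.59 after median-of-ratios scaling, camera BH-adjusted p = 0.00236, adjusted p = 0.501 with an estimated correlation). They had 0 of 28 members called by limma. At 4 h with 5G6 they were called as well (median log2 fold change 0.51 over 28 members, 0.36 after median-of-ratios scaling, camera BH-adjusted p = 1.4e-05, adjusted p = 0.559 with an estimated correlation), and camera did not call them without 5G6 replicate 2 (median -0.01).

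Interferon genes differed between replicates in every group. After median-of-ratios scaling the median of replicate 1 minus replicate 2 was 1.07 to 1.65 over the 8 groups. Against the DMSO library of the same number the median was 0.10 to 0.81 in the 6 libraries of the compounds at 48 h and -0.35 to 0.01 at 4 h. The labels do not pair replicates by number. At 48 h camera called the list for 5G6 (median log2 fold change 0.51 over 25 members, 0.61 after median-of-ratios scaling, camera BH-adjusted p = 0.00822, adjusted p = 0.690 with an estimated correlation), with no member called by limma and medians of -0.32 without DMSO replicate 2 and 1.13 without 5G6 replicate 2, but not for 6D7 (adjusted p = 0.825). For 7F8 it was called (median log2 fold change 0.53 over 25 members, 0.77 after median-of-ratios scaling, camera BH-adjusted p = 3.3e-05, adjusted p = 0.512 with an estimated correlation) with 1 member called higher, 0 lower and 24 not called, with 0 higher and 0 lower adjusted over the list alone, and the medians were -0.40 and 1.34 without 7F8 replicate 1 and replicate 2.

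Mitochondrially encoded genes matched no tested gene name, and only 3 fibroblast and endothelial markers passed the filter, so these lists were not run.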
